A study of Homo sapiens with 6 samples.

How the data were processed

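RNA of hTERT-RPE1 cells, grown to confluence and lysed in Trizol, was labelled with biotin by an in vitro transcription kit that starts from the 3-prime end of transcripts and hybridised to Affymetrix U133 Plus 2.0 arrays, per the labels' protocols. Groups and replicate numbers came from the sample titles, with 3 control and 3 GFP-MFRP arrays. The values analysed are the deposited log2 values of the authors, made with Affymetrix Expression Console and Robust Multichip Analysis (RMA), per the series design text and the submitters' processing notes. RMA corrects background, equalises the value distributions of the arrays by quantile normalisation and summarises the probes of a set. Software versions are not given in the sources used here. Because quantile normalisation makes the arrays' distributions alike, a shift shared by most transcripts would be removed, and differences are relative to the bulk of probe sets. The lowest value of an array lay between 1.29 and 1.39 and the highest between 13.6 and 13.7, and the quartiles of control replicate 1 were 3.64, 5.03 and 6.77. No detection calls were used and no counts lie behind the values, so the number of arrays limits the precision.

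Probe sets were named through the annotation table of the array. Of 54613 probe sets, 41091 had 1 gene, 1801 had several and 11721 had no listed gene, and sets with several genes named none. Symbols were updated through the gene identifier and the RefSeq table of assembly GRCh38.p14, which matched 41037 of the 41091. Affymetrix control probe sets were not analysed here, so the planned comparison of 3-prime with 5-prime signal of control transcripts, and its alternative with the middle signal, were not run. The planned value for MFRP alone was not given, since no probe set names it alone. Instead, the 2 probe sets annotated jointly to C1QTNF5 and MFRP are reported.

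Differences were tested with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with a mean-variance trend, as GFP-MFRP minus control, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are the moderated ones of that fit. At the gene level each of 19775 genes was read by the probe set with the highest mean over the 6 arrays among sets naming that gene alone. The 30 gene lists cover the pigment epithelium, Wnt signalling, matrix, stress, growth, inflammation and markers of other cell types, and 762 of their 836 listed genes were measured. Lists with at least 5 members and the 23 chromosomes 1 to 22 and X were tested with camera at a preset inter-gene correlation of 0.01. Counts adjusted over the list alone take the same p-values and adjust them within the list. The lists, tests, alternatives and the rule for naming genes were fixed before the data were examined. The rule named the 12 largest rises and the 12 largest falls in log2 among called genes whose groups did not overlap, and for each list up to 4 called members with the largest change, or the member with the largest change where none was called. Genes outside the rule are said to have been named after their values were seen. Of the 112 genes the rule named, 45 were read by _s_at and 4 by _x_at probe sets and 28 have probe sets that disagree in sign, and none changed direction under the other normalisations. Probe sets of the same sign but near 0 are given for the 12 largest rises and 12 largest falls, and not for every other gene.

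The gene-level fit was tested on simulated data of 19775 genes for this comparison, with changes planted in some. It recovered 40.3% of genes changed by a log2 difference of 0.5, 80.6% of those changed by 1 and 97.0% of those changed by 2, and 5 of 150 calls (3.33%) were false. A simulated shift of 0.3 in the YAP/TAZ list was found and 0 other lists were called. The simulated genes varied independently of each other and with the same spread in both groups. Neither result therefore shows how the tests perform on correlated genes. Changes of 0.5, 1 and 2 were planted in 67, 67 and 66 genes, whereas 1984 genes were called in the data. The Benjamini-Hochberg adjustment depends on the share of changed genes, so the recovered shares need not hold for these data.

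The alternatives were a repeated quantile normalisation, a common median, cyclic loess, eBayes without the trend or with robust settings, array weights, filters at a mean of 5 and 6, each array left out, the replicate number as a block, other rules for the probe set of a gene, an unmoderated test, other thresholds (adjusted p under 0.01, a log2 difference of at least 1, limma treat with 1.5-fold), camera with an estimated correlation or on ranks, and fry. Removal of the trend with gene length and mean level from each array, by loess with a span of 0.3, was chosen after seeing the data, as were the gene families of the closing section. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.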

Results

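Transcript levels were measured on 6 arrays of hTERT-RPE1 cells, a human retinal pigment epithelium line immortalised with telomerase. On 3 arrays the RNA came from control cells and on 3 from cells that overexpressed GFP-MFRP, a construct of membrane frizzled-related protein, a transmembrane protein of the retinal pigment epithelium, named with green fluorescent protein. Each array gave log2 values for 54613 probe sets, and the array medians lay between 5.02 and 5.04. Across probe sets, which are not independent replicates, Pearson's r was 0.996 to 0.997 between control arrays, 0.991 to 0.993 between GFP-MFRP arrays and 0.984 to 0.992 between the groups. The first principal component held 53.8% of the variance and parted the groups, with GFP-MFRP replicate 2 at 0.14 and replicates 1 and 3 at 0.51. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

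The transgene itself was examined through the only probe sets that name it, 2 sets annotated jointly to C1QTNF5 and MFRP, which are neighbouring genes. The dimmer set rose from 6.05 ± 0.14 (SD, n = 3) in control cells to 6.67 ± 0.17 (SD, n = 3) in GFP-MFRP cells, a log2 difference of 0.61 ± 0.13 (SE, limma adjusted p = 0.0285). Its values were 6.15, 5.90 and 6.11 on the control arrays and 6.85, 6.51 and 6.64 on the GFP-MFRP arrays. The brighter set read 6.95 ± 0.07 and 6.97 ± 0.08 (SD, n = 3 each), a difference of 0.02 ± 0.11 (SE, limma adjusted p = 0.959). Neither value belongs to MFRP alone, and a probe set outside the sequence of the construct checks nothing. The call for the dimmer set was lost without control replicate 1, 2 or 3 (adjusted p = 0.0785, 0.143 and 0.0999) and without GFP-MFRP replicate 3 (0.0587). The difference of the brighter set was -0.02 without control replicate 3 and -0.02 without GFP-MFRP replicate 1.

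The comparison of GFP-MFRP with control cells asks which transcripts change with MFRP overexpression. CCL2, a chemokine that attracts monocytes, fell from 9.56 ± 0.25 to 4.44 ± 0.24 (SD, n = 3 each), 34.8-fold lower (limma adjusted p = 6.36e-08). CXCL8, a neutrophil chemokine, was 7.37-fold lower. The urea transporter SLC14A1 went from 7.14 ± 0.32 to 3.80 ± 0.15 and the kinase NRK from 6.57 ± 0.07 to 2.93 ± 0.20 (SD, n = 3 each). HOXB3, a homeobox transcription factor, fell from 7.72 ± 0.17 to 5.01 ± 0.13 (SD, n = 3 each). The steroid-reducing enzyme AKR1C3 fell by 2.27 ± 0.15 (SE) on the log2 scale, THBD, the thrombin receptor thrombomodulin, by 2.22 ± 0.11, and the membrane-type metalloprotease MMP16 by 2.21 ± 0.25. CHI3L1, a secreted chitinase-like glycoprotein, fell from 5.83 ± 0.08 to 3.73 ± 0.27 and the histone deubiquitinase MYSM1 from 7.84 ± 0.20 to 5.84 ± 0.51 (SD, n = 3 each). CEP15 went from 6.10 ± 0.10 to 3.29 ± 0.20 and TRIM61 from 6.17 ± 0.14 to 3.74 ± 0.32 (SD, n = 3 each). These 12 falls had adjusted p-values from 6.36e-08 to 0.000652.

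SLC1A1, a sodium-dependent glutamate transporter, showed the largest rise, from 4.45 ± 0.13 to 8.39 ± 0.36 (SD, n = 3 each), 15.4-fold higher (limma adjusted p = 8.13e-07). PLXDC2, a membrane protein with a plexin domain, went from 3.36 ± 0.39 to 5.70 ± 0.08 (SD, n = 3 each), and IGFBP5, a secreted binding protein of insulin-like growth factors, was 4.90-fold higher. PNPLA4, of the patatin-like phospholipase family, rose by a log2 difference of 2.16 ± 0.16 (SE), the membrane-skeleton protein ADD2 by 2.08 ± 0.16, the cell-adhesion protein NFASC by 1.93 ± 0.12 and the orphan receptor GPR160 by 1.92 ± 0.13. ANGPTL4, a secreted inhibitor of lipoprotein lipase, went from 7.65 ± 0.14 to 9.45 ± 0.13 (SD, n = 3 each). The long noncoding RNAs LINC02901, from 3.85 ± 0.19 to 5.72 ± 0.17 (SD, n = 3 each), and LINC01116, 3.28-fold, were higher. The hair keratin-associated protein KRTAP1-5 was 3.21-fold higher and the caveolar coat protein CAVIN2 went from 3.86 ± 0.21 to 5.52 ± 0.21 (SD, n = 3 each). These 12 rises had adjusted p-values from 8.13e-07 to 6.45e-05.

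All 24 of these genes kept their call with each array left out in turn, with adjusted p up to 0.00578. The lower quartile of an array lay between 3.61 and 3.66, and means near or under it, as for NRK, CEP15, TRIM61, CHI3L1 and SLC14A1 in GFP-MFRP cells and PLXDC2, LINC02901 and CAVIN2 in control cells, are not shown to exceed background. PNPLA4, ANGPTL4, CCL2, THBD and CHI3L1 were read by _s_at probe sets, which can match several transcripts, and CXCL8 and TRIM61 by _x_at sets, whose probes can match other sequences. For NRK, HOXB3 and MMP16 another probe set of the gene lay at 0.03, 0.02 and 0.22, opposite in sign to the fall. The probe set nearest 0 kept the sign but was small for CEP15 (-0.09), CHI3L1 (-0.02), MYSM1 (-0.10), ADD2 (0.02), IGFBP5 (0.07) and PLXDC2 (0.21). It lay at 0.38 for NFASC, 0.56 for CAVIN2, 0.65 for PNPLA4, -0.72 for TRIM61, -0.91 for THBD and 1.03 for SLC1A1. For ANGPTL4, CXCL8 and SLC14A1 it lay at 1.76, -1.70 and -3.34.

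**Figure D1:**
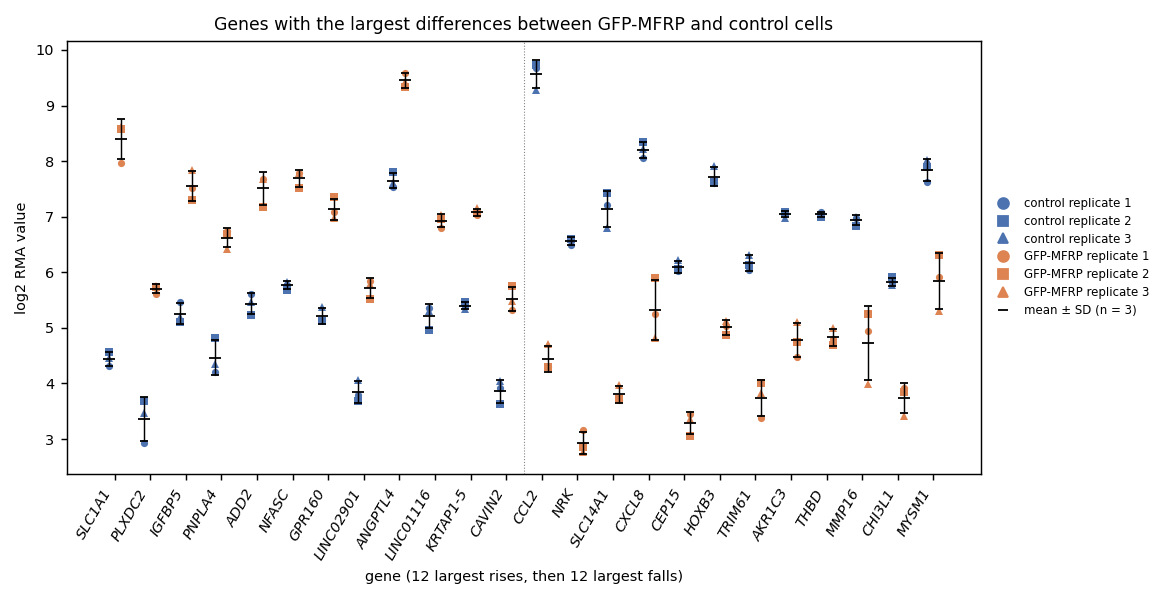
Log2 RMA values (vertical axis) of the 12 genes with the largest rises and the 12 with the largest falls, with a symbol per array, control in blue and GFP-MFRP in orange, and bars for the mean ± SD of 3 arrays. The groups do not overlap for any of these genes, and the GFP-MFRP arrays spread most in MMP16, with an SD of 0.66.

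Of 19775 genes, each read by 1 probe set, 1984 differed at a limma adjusted p under 0.05, 884 higher and 1100 lower in GFP-MFRP cells. Differences of at least 2-fold were more often falls, with 229 genes lower and 50 higher, while limma treat at 1.5-fold called 42 lower and 32 higher. The groups did not overlap in 29.3% of all genes, where chance gives 10%. At the level of probe sets, 3365 of 54613 differed, 1407 higher and 1958 lower. Without control replicate 1, 2 or 3 the gene count was 899, 751 and 791 and the probe set count 788, 547 and 652, and without GFP-MFRP replicate 3 the probe set count was 2055. The share of called genes that were higher was 44.6%, and after cyclic loess normalisation it was 30.1%. Pairs of control arrays differed with an SD of 0.178 to 0.207 and pairs of GFP-MFRP arrays with 0.271 to 0.319.

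Of the 30 gene lists, 10 shifted as a group by the camera test with its preset correlation, 3 upward and 7 downward, and none did so with the correlation estimated from the residuals, where the lowest adjusted p was 0.0901. At an unadjusted p under 0.05 there were 12 lists, and fry, which tests a list without comparing it with other genes, gave 8. For the NF-kB and primary cilium lists the estimated correlation was -0.018 and -0.009, below the preset 0.01, yet their adjusted p rose to 0.0901. A higher correlation therefore cannot explain why these calls were lost, and what did was not tested. Each of the other called lists lay above the preset value, from 0.015 (p53 targets) to 0.19 (lysosome). Every difference below is GFP-MFRP minus control on the log2 scale, ± SE, with n = 3 arrays per group.

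Members of the NF-kB, interferon and complement lists fell more often than they rose. In the list of NF-kB cytokines and chemokines, 7 of 30 measured members fell and 1 rose, with 9 lower and 1 higher adjusted over the list alone (camera adjusted p = 8.76e-05, fry adjusted p = 0.00129; adjusted p = 0.0901 with an estimated correlation). The list median was -0.10 and the mean -0.45, with CCL2 at -5.12 and CXCL8 at -2.88, so the mean rests much on these genes. Besides CCL2 and CXCL8, the cytokine IL1B was 2.82-fold lower and NFKBIZ, an atypical member of the NF-kB inhibitor family, fell by 1.15 ± 0.19. The member that rose, named after its value was seen, was IL6, by 0.46. In the type I interferon list 10 of 38 members fell and 1 rose, with 13 lower and 1 higher adjusted over the list alone (median -0.14; camera adjusted p = 1.07e-05, fry adjusted p = 0.00331; adjusted p = 0.0901 with an estimated correlation). The helicases DDX60 and IFIH1 fell by 1.52 ± 0.17 and 0.87 ± 0.20, IFI44L by 1.16 ± 0.15 and the antiviral membrane protein IFITM1 by 0.95 ± 0.13, while ISG15, named after its value was seen, was 0.50 higher. Complement components fell in 4 of 27 cases with no rise, and 7 adjusted over the list alone (camera adjusted p = 0.00743, fry adjusted p = 0.103; adjusted p = 0.63 with an estimated correlation). These were C5 by 1.03 ± 0.12, the proteases C1R by 0.95 ± 0.12 and C1S by 0.92 ± 0.12, and the factor I gene CFI by 0.40 ± 0.09, to a mean of 3.59 that is under the lower quartile of the arrays and not shown to exceed background. Without GFP-MFRP replicate 2 the complement list, with a median of -0.01 over all arrays and 0.01 without that array, was not past the threshold (adjusted p = 0.082). The calls of IFIH1 and CFI were lost without any of the control arrays, with an adjusted p of up to 0.0746 for IFIH1 (control replicate 1) and 0.109 for CFI (control replicate 2), and that of IFIH1 also without GFP-MFRP replicate 1 (0.0561). IL6 and ISG15 likewise lost their calls without any of the control arrays, up to 0.136 for IL6 (control replicate 1) and 0.113 for ISG15 (control replicate 2). DDX60, IFITM1, ISG15, NFKBIZ, C1R and C1S were read by _s_at sets, and another probe set of IFIH1 lay at 0.23.

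Members of the lists of p53 targets and of targets of YAP and TAZ, coactivators of the Hippo pathway, rose more often than they fell. Among YAP/TAZ targets 9 of 21 members rose and none fell, with 12 adjusted over the list alone, and the list median was 0.30 (camera adjusted p = 0.00034, fry adjusted p = 0.00199; adjusted p = 0.143 with an estimated correlation). IGFBP3 rose by 1.35 ± 0.07, the muscle ankyrin repeat protein ANKRD1 by 1.29 ± 0.13, the Hippo regulator WWC1 by 0.67 ± 0.12 and FJX1 by 0.67 ± 0.13. Of the p53 targets 6 of 21 rose and none fell, and 11 were higher and 2 lower adjusted over the list alone (median 0.28; camera adjusted p = 0.00245, fry adjusted p = 0.00331; adjusted p = 0.163 with an estimated correlation). The cell cycle inhibitor CDKN1A was 2.06-fold higher, from 9.45 ± 0.14 to 10.49 ± 0.08 (SD, n = 3 each), the nuclease AEN rose by 0.72 ± 0.11, GADD45A by 0.71 ± 0.09 and the DNA polymerase POLH by 0.68 ± 0.14. In the ATF4 stress list 9 of 30 rose and 2 fell, with 10 higher and 4 lower adjusted over the list alone (median 0.14; camera adjusted p = 0.0217, fry adjusted p = 0.0828; adjusted p = 0.742 with an estimated correlation). The amino acid transporter SLC7A5 rose by 0.96 ± 0.12, the lipoprotein receptor VLDLR by 0.70 ± 0.14 and the transcription factor ATF3 by 0.62 ± 0.10, while DDIT4, an inhibitor of mTORC1 signalling, fell by 1.16 ± 0.10 and CEBPB, named after its value was seen, fell by 0.34. That list was not past the threshold without GFP-MFRP replicate 1 (adjusted p = 0.0578). The unfolded protein response list was not past it (4 of 25 rose, 6 adjusted over the list alone; camera adjusted p = 0.0543, fry adjusted p = 0.0182), though without control replicate 2 or GFP-MFRP replicate 1 it was (0.0357 and 0.00338). Its risen members were SDF2L1 with 0.65 ± 0.11, DERL2 with 0.39 ± 0.09, MANF with 0.34 ± 0.08 and the chaperone HSPA5 with 0.29 ± 0.06. Calls were lost with an array left out, with the highest adjusted p without control replicate 1 for HSPA5 (0.0632), CEBPB (0.149), without control replicate 2 for FJX1 (0.0684), POLH (0.0715) and without control replicate 3 for VLDLR (0.0645), DERL2 (0.108), MANF (0.1). IGFBP3, WWC1, CDKN1A, AEN, SLC7A5, VLDLR, ATF3, DDIT4 and SDF2L1 were read by _s_at sets, and another probe set of WWC1 and of ATF3 lay at -0.02 and -0.07.

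Members of the primary cilium and proliferation lists fell more often than they rose. In the primary cilium list, whose median of -0.22 was the lowest of the 30, 7 of 31 members fell and 1 rose, with 10 lower and 1 higher adjusted over the list alone (camera adjusted p = 3.07e-05, fry adjusted p = 0.00331; adjusted p = 0.0901 with an estimated correlation). The intraflagellar transport genes IFT80, IFT81 and IFT88 fell by 1.49 ± 0.17, 1.10 ± 0.13 and 0.82 ± 0.13, and CEP290, a protein of the ciliary transition zone, by 1.24 ± 0.24. BBS5, named after its value was seen, was 0.40 higher, with both means, 3.08 and 3.48, under the lower quartile of the arrays and not shown to exceed background. In the proliferation list 9 of 40 members fell and 2 rose, with 11 lower and 3 higher adjusted over the list alone (median -0.12; camera adjusted p = 0.0074, fry adjusted p = 0.242; adjusted p = 0.636 with an estimated correlation). The spindle protein ASPM fell by 1.25 ± 0.23, the centromere proteins CENPF and CENPE by 1.23 ± 0.22 and 1.10 ± 0.24, and the topoisomerase TOP2A by 0.93 ± 0.24, while CDC6 and CCNB1, named after their values were seen, were 0.69 and 0.39 higher. With an array left out some calls were lost, with the highest adjusted p without control replicate 1 for CEP290 (0.0515), without control replicate 2 for TOP2A (0.119), BBS5 (0.115), CCNB1 (0.085) and without control replicate 3 for CENPE (0.0787). IFT80, CEP290, ASPM, CENPF, TOP2A and CCNB1 were read by _s_at sets, and another probe set of IFT80, IFT81 and CEP290 lay at 0.30, 0.08 and 0.06.

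Long genes were lower in GFP-MFRP cells relative to short ones, a relation examined after it was seen in the data. Across 9713 genes with a mean of at least 6, gene length in the GRCh38.p14 annotation and the log2 difference had a Spearman correlation of -0.24, and -0.14 without GFP-MFRP replicate 1. The median difference was 0.11 in the shortest 972 of these genes and -0.07 in the longest 972, or 0.07 and -0.01 without that array. Genes of the primary cilium list had a median length of 52.3 kb and those of the proliferation list 23.4 kb, and with the length trend removed both lists still shifted downward at the preset correlation (camera adjusted p = 0.000452 and 0.00285). Without that removal, the adjusted p was 0.0901 and 0.636 with an estimated correlation.

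**Figure D2:**
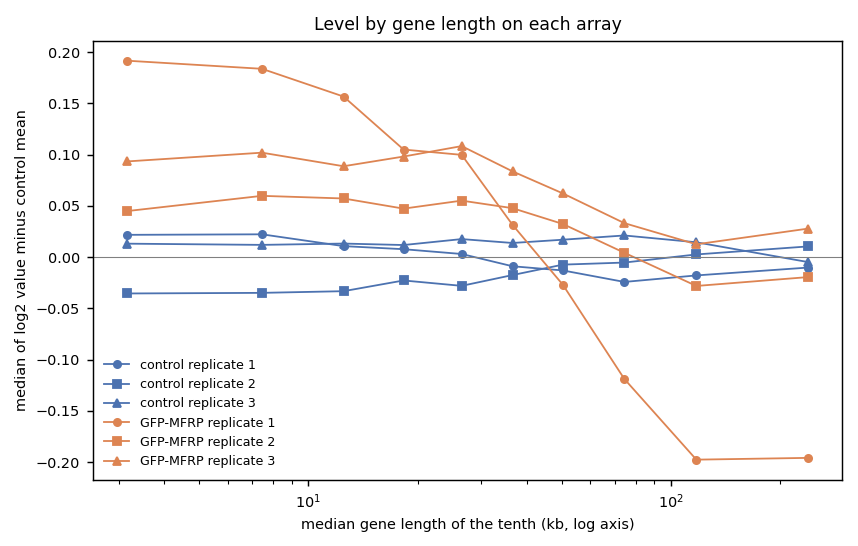
Median of log2 value minus control mean (vertical axis) in 10 equal bins of 9713 genes ordered by gene length (horizontal axis, kb, log scale), with a line per array, control in blue and GFP-MFRP in orange. GFP-MFRP replicate 1 runs from 0.19 in the bin of shortest genes to -0.20 in that of the longest, and replicates 2 and 3 from 0.04 and 0.09 to -0.02 and 0.03.

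Among interstitial collagens and elastic fibres 4 of 36 members fell and none rose, over all genes and adjusted over the list alone, and the list shifted downward by camera but not by fry (median -0.06; camera adjusted p = 0.0245, fry adjusted p = 0.103; adjusted p = 0.636 with an estimated correlation). POSTN, or periostin, fell from 6.09 ± 0.08 to 4.32 ± 0.10 (SD, n = 3 each), and COL1A1 fell by 1.11 ± 0.13, the tenascin TNC by 0.65 ± 0.13 and COL12A1 by 0.59 ± 0.12. This list was not past the threshold without control replicate 1 (adjusted p = 0.0626) or GFP-MFRP replicate 2 (0.139), nor with the length trend removed (0.22). Basement membrane genes did not shift as a list (4 of 26 rose and 1 fell, also adjusted over the list alone; camera adjusted p = 0.787), yet the collagen IV chains COL4A4 and COL4A3 rose by 1.12 ± 0.22 and 1.02 ± 0.27 and the laminin LAMB3 by 0.89 ± 0.11, while LAMA4 fell by 0.97 ± 0.17. Matrix proteases and inhibitors gave 2 rises and 3 falls among 34 members, 4 and 3 adjusted over the list alone (camera adjusted p = 0.816). Besides MMP16, ADAMTS1 rose by 1.36 ± 0.12 and ADAMTS5 by 0.70 ± 0.18, and ADAMTS3 fell by 1.03 ± 0.16. Leaving out an array ended calls, with the highest adjusted p without control replicate 1 for COL4A4 (0.0516), without control replicate 2 for TNC (0.0647), COL12A1 (0.0731) and without control replicate 3 for COL4A3 (0.131), ADAMTS5 (0.116). POSTN, COL1A1, LAMA4 and ADAMTS1 were read by _s_at sets, and probe sets of COL1A1, TNC, COL12A1, COL4A4 and LAMA4 disagreed in sign. Another probe set of POSTN lay at -0.05.

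TGF-beta targets moved both ways, with 6 of 26 higher and 5 lower, 7 and 5 adjusted over the list alone (camera adjusted p = 0.87). The cytokine IL11 rose by 0.78 ± 0.12, while SKIL, an inhibitor of SMAD signalling, fell by 1.13 ± 0.20, the receptor TGFBR1 by 0.73 ± 0.18 and ID1 by 0.71 ± 0.09. In the list of mesenchymal transition 3 of 20 rose and 5 fell, 3 and 7 adjusted over the list alone (camera adjusted p = 0.0709; fry adjusted p = 0.0102). The transcription factors ZEB1 and ZEB2 fell by 1.23 ± 0.19 and 0.76 ± 0.15, the protease FAP by 1.10 ± 0.12 and the growth factor receptor PDGFRA by 0.92 ± 0.16. Epithelial junction and keratin genes gave 2 rises and 3 falls among 29, 2 and 4 adjusted over the list alone (camera adjusted p = 0.626). The desmosomal genes DSC2 and JUP fell by 0.77 ± 0.18 and 0.74 ± 0.12, while PKP2, also desmosomal, and the claudin CLDN11 rose by 0.65 ± 0.15 and 0.47 ± 0.12. The calls lost when an array was left out had the highest adjusted p without control replicate 1 for DSC2 (0.0874), PKP2 (0.0969), without control replicate 2 for TGFBR1 (0.119), CLDN11 (0.196) and without control replicate 3 for ZEB2 (0.0537). TGFBR1, ID1, FAP, ZEB2, JUP and PKP2 were read by _s_at sets, and probe sets of SKIL, TGFBR1, PDGFRA, ZEB2, DSC2 and CLDN11 disagreed in sign.

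Genes of the retinal pigment epithelium and of Wnt signalling changed singly rather than as lists. Of the pigment epithelium identity and visual cycle genes 4 of 25 rose and 1 fell, 5 and 3 adjusted over the list alone (camera adjusted p = 0.671). RDH10, a retinol dehydrogenase of the visual cycle, rose by 0.73 ± 0.12, the keratin KRT18 by 0.44 ± 0.05 and ezrin, EZR, by 0.40 ± 0.10, while the integrin ITGAV fell by 1.02 ± 0.13. In the pigmentation list 1 of 17 rose, also adjusted over the list alone (camera adjusted p = 0.846), HPS1 by 0.61 ± 0.13. Of the Wnt/beta-catenin targets 3 of 22 rose and none fell, also adjusted over the list alone (camera adjusted p = 0.567). They were the Wnt inhibitor DKK1, from 9.60 ± 0.19 to 10.58 ± 0.13 (SD, n = 3 each), the cyclin CCND1 with 0.53 ± 0.13 and BMP4 with 0.50 ± 0.11. Frizzled receptors, Wnt ligands and antagonists gave 1 rise and 3 falls among 40, also adjusted over the list alone (camera adjusted p = 0.68). The ligand WNT5B rose by 0.58 ± 0.12, and the coreceptor LRP6 fell by 0.83 ± 0.18, the receptor FZD6 by 0.59 ± 0.15 and the secreted antagonist SFRP1 by 0.17 ± 0.04. Of the C1q/TNF-related proteins 1 of 11 rose, also adjusted over the list alone (camera adjusted p = 0.309), C1QTNF2 by 0.53 ± 0.13. Of the genes of eye size and inherited retinal disease 1 of 22 fell, also adjusted over the list alone (camera adjusted p = 0.567), the eye-field transcription factor SIX3 by 0.49 ± 0.09. Calls were lost with an array left out, with the highest adjusted p without control replicate 1 for SFRP1 (0.142), without control replicate 2 for EZR (0.141), HPS1 (0.0898), CCND1 (0.126), LRP6 (0.0878), WNT5B (0.071), C1QTNF2 (0.137) and without control replicate 3 for BMP4 (0.0892), FZD6 (0.132). KRT18 was read by an _x_at set and EZR, BMP4, WNT5B, SFRP1 and SIX3 by _s_at sets, and probe sets of HPS1, LRP6 and SFRP1 disagreed in sign.

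Lysosomal genes fell in 7 of 30 cases and rose in 3, 9 and 4 adjusted over the list alone (median -0.09; camera adjusted p = 0.0349, fry adjusted p = 0.258; adjusted p = 0.745 with an estimated correlation). The melanosomal glycoprotein GPNMB fell by 0.50 ± 0.09 and the cathepsins CTSF and CTSH by 0.46 ± 0.11 and 0.44 ± 0.11, while cathepsin C, CTSC, was 1.77-fold higher, from 10.93 ± 0.12 to 11.75 ± 0.05 (SD, n = 3 each). The list was not past the threshold without control replicate 1 or 3 (adjusted p = 0.0745 and 0.0527) or GFP-MFRP replicate 2 (0.108). The NRF2 antioxidant list gave 3 rises and 3 falls among 22, 4 and 3 adjusted over the list alone (camera adjusted p = 0.87). AKR1C3 and the exporter ABCC3, from 6.99 ± 0.03 to 5.99 ± 0.19 (SD, n = 3 each), were lower, AKR1B10 fell by 0.52 ± 0.09, and GCLM, a subunit of the enzyme that starts glutathione synthesis, rose by 0.54 ± 0.13. Of the hypoxia and angiogenesis genes 4 of 30 rose and 1 fell, 6 and 1 adjusted over the list alone (camera adjusted p = 0.626; fry adjusted p = 0.042). Besides ANGPTL4, the growth factor FGF1 rose by 0.79 ± 0.15, hexokinase HK2 by 0.59 ± 0.09 and the prolyl hydroxylase P4HA2 by 0.44 ± 0.08. Cholesterol synthesis gave 2 falls among 19, also adjusted over the list alone (camera adjusted p = 0.68), INSIG1 by 0.67 ± 0.15 and STARD4 by 0.57 ± 0.15. With an array left out some calls were lost, with the highest adjusted p without control replicate 1 for CTSH (0.13), GCLM (0.1), INSIG1 (0.0854), without control replicate 2 for CTSF (0.128), P4HA2 (0.0609) and without control replicate 3 for STARD4 (0.181). CTSC, CTSF, CTSH, ABCC3 and AKR1B10 were read by _s_at sets, and probe sets of GPNMB, ABCC3, GCLM and P4HA2 disagreed in sign.

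Markers of other cell types showed few differences. No endothelial marker of 14, haematopoietic marker of 15 or ribosomal protein gene of 28 passed the limma threshold, over all genes or adjusted over the list alone (camera adjusted p = 0.787, 0.816 and 0.567). Their largest differences were 0.33 ± 0.10 for EGFL7, 0.40 ± 0.14 for TYROBP and -0.10 ± 0.06 for RPL7, which an _x_at set read and whose probe sets disagreed in sign. TYROBP, at 3.54 in control cells, was under the lower quartile of the arrays and is not shown to exceed background there. It gained a call with 1 array left out. With the length trend removed the ribosomal list had a camera adjusted p of 0.0386, with a median of -0.03. Of the photoreceptor markers 1 of 18 rose, also adjusted over the list alone (camera adjusted p = 0.634), PDE6A by 0.44 ± 0.11. Of the fibroblast and myogenic markers 1 of 15 fell and none did adjusted over the list alone (camera adjusted p = 0.988), HOXC6 by 0.44 ± 0.12, on an _s_at set. Leaving out an array ended calls, with the highest adjusted p without control replicate 2 for HOXC6 (0.178) and without control replicate 3 for PDE6A (0.131).

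**Figure D3:**
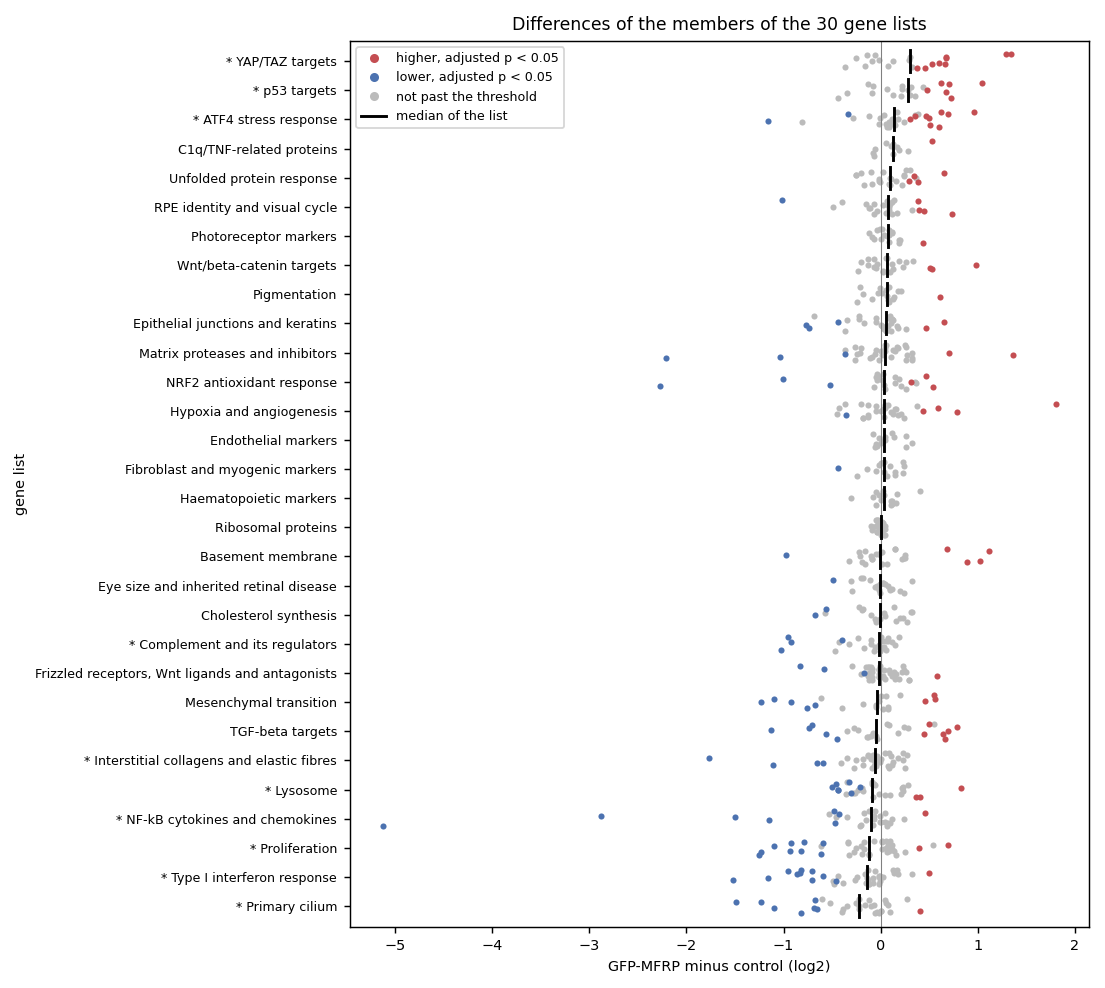
Difference between GFP-MFRP and control cells (horizontal axis, log2) of each measured member of the 30 gene lists (vertical axis, ordered by median), with members past the limma threshold in red if higher and blue if lower, black bars for medians and an asterisk for the 10 lists with a camera adjusted p under 0.05. Medians run from -0.22 for the primary cilium list to 0.30 for YAP/TAZ targets, and CCL2 at -5.12 lies farthest from 0.

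In 5 lists the median, the mean and the direction of the test differed in sign. The median and mean were -0.00 and 0.09 for basement membrane genes, 0.04 and -0.01 for matrix proteases, -0.05 and 0.01 for TGF-beta targets, 0.05 and -0.04 for epithelial junctions and 0.04 and -0.04 for NRF2 genes, and the test pointed up for the basement membrane and NRF2 lists and down for the other three.

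Chromosomes were compared to ask whether a whole chromosome shifted, as in a population with another karyotype. By camera 0 of 23 chromosomes passed, 2 had an unadjusted p under 0.05, and neither the estimated correlation nor fry gave any. Chromosome 22, with 19 genes higher and 4 lower of 460, had the lowest adjusted p, 0.13, and a median difference of 0.09. It passed upward without control replicate 1 (adjusted p = 0.0453) and without GFP-MFRP replicate 2 (0.0151). Median differences lay between 0.01 and 0.09 on all chromosomes, against 0.04 over all genes. For 14 of the 23 the sign of the mean or of the test differed from that of the median. Among genes with a mean of at least 5, chromosome 13 passed downward (camera adjusted p = 0.00255, median -0.12) and chromosome 22 upward (0.0212, median 0.10). With a mean of at least 6 chromosome 4 also passed downward (0.0381), and chromosomes 17 and 19 upward (0.0379 and 0.0289). Their median differences were -0.03, 0.10 and 0.11, and those of chromosomes 13 and 22 were then -0.15 and 0.12. Over all genes, the estimated correlation was 0.14, 0.16 and 0.23 for chromosomes 17, 19 and 22, above the preset 0.01. For chromosomes 4 and 13 it was 0.001 and 0.003. The filtered tests were not repeated with an estimated correlation or with the length trend removed.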

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

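Under 20 other settings the YAP/TAZ, p53, interferon, NF-kB and cilium lists kept their call in 19 each, all but the estimated correlation, and the proliferation list in 18, complement in 17, ATF4 in 16, interstitial collagens in 11 and lysosome in 10. Among these 10 lists a median changed sign only for complement without GFP-MFRP replicate 2 (0.01). Array weights gave 6327 probe sets and 3741 genes, an unmoderated t-test 27 and 72, an adjusted p under 0.01 614 and 656, a log2 difference of at least 1 625 and 279, and limma treat at 1.5-fold 78 (38 higher and 40 lower) and 74 (32 and 42). With 1 array left out the counts ran from 547 (without control replicate 2) to 4927 probe sets (without GFP-MFRP replicate 2), 751 to 2740 genes, 7 to 11 lists and 0 to 1 chromosomes. Cyclic loess left 1778 genes, 535 higher and 1243 lower. The cause of these differences was not tested.

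For the dimmer joint probe set, whose log2 difference was 0.61, the adjusted p was 0.174 with the unmoderated test and 1 with limma treat, and its value of 0.0285 is over 0.01. With 1 array left out its difference ran from 0.52 to 0.69 and its adjusted p from 0.0195 (without GFP-MFRP replicate 2) to 0.143 (without control replicate 2). The brighter joint set changed sign with cyclic loess (-0.0476), without control replicate 3 and without GFP-MFRP replicate 1, and ran from -0.0240 (without GFP-MFRP replicate 1) to 0.0543 (without GFP-MFRP replicate 2) with 1 array left out. With probe sets without x, s or a suffixes preferred, ATF3 (-0.0737), CEP290 (0.0552) and RPL7 (0.180) changed sign, because another probe set then reads the gene. Of the other results for named genes, 333 lost and 4 gained a call. The 4 gains lie among EGFL7, TYROBP and RPL7, the only genes named by the rule that the main fit did not call. The estimated correlation gave 0 gene lists. Filters at a mean of 5 and 6 gave 2 and 5 chromosomes.

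With the replicate number as a block there were 2939 probe sets, 1966 genes, 10 lists and 0 chromosomes, and the dimmer joint set had a log2 difference of 0.61 with an adjusted p of 0.0313. The deviations of same-numbered arrays correlated with 0.18, 0.30 and -0.26, so not every array went with its own number and the numbers were not taken to pair the arrays. The comparison of 3-prime with 5-prime signal and its alternative were not run, because control probe sets were not analysed here, and robust eBayes was run only for probe sets and genes, as camera does not use it.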

Other observations

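The tests on gene length, on probe sets outside the construct and on blood cells, and those on gene families, were chosen after the results they concern were seen, whereas the splits of the arrays and the test of group labels were planned.

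Among 349 families of genes that share a symbol stem, 13 shifted by camera, 8 upward and 5 downward, 5 of these 13 with the length trend removed, and 0 with an estimated correlation, where the lowest adjusted p was 0.997. As for the gene lists, the loss of every call with an estimated correlation need not come from correlation between genes. Of the 13, 7 stayed past the threshold without GFP-MFRP replicate 1, 5 upward and 2 downward. Without control replicate 1 the count was 9, and with cyclic loess 8. Genes with the stem CEP, most of them coding for centrosomal proteins, shifted downward, with 14 of 38 lower and none higher (camera adjusted p = 3.19e-06, 0.00118 with the length trend removed; 0.997 with an estimated correlation). CEP152, needed for centriole duplication, fell by 0.97 ± 0.14 (SE, n = 3 per group), CEP97 by 1.21 ± 0.22 and CEP57 by 0.90 ± 0.16. Of the 8 genes with the stem SMC, which are SMC5-DT, a divergent transcript, and 7 genes for subunits of cohesin, condensin and the SMC5/6 complex, 4 fell and none rose (camera adjusted p = 0.00397, 0.014 with the length trend removed; 0.997 with an estimated correlation): SMC5 by 1.33 ± 0.20, SMC3 by 1.24 ± 0.14, SMC4 by 1.13 ± 0.19 and SMC6 by 0.69 ± 0.18. The call of SMC6 was lost without any control array and without GFP-MFRP replicate 3 (adjusted p up to 0.143, without control replicate 3). Genes with the stem RRP, for ribosomal RNA processing, shifted upward, with 4 of 8 higher (camera adjusted p = 0.0023, 0.00493 with the length trend removed; 0.997 with an estimated correlation), among them RRP12 by 0.67 ± 0.12. Genes with the stem MRPL, most of them for the large mitochondrial ribosomal subunit, had a median of 0.20, with 3 of 50 higher and none lower (camera adjusted p = 0.000493, 0.0305 with the length trend removed; 0.997 with an estimated correlation). These 4 families stayed past the camera threshold with each array left out, but not all of their called members did. Without control replicate 1, 2 or 3 the CEP genes called lower were 8, 9 and 8 and the RRP genes called higher 1, 1 and 2, and without GFP-MFRP replicate 1 or 3 the RRP count was 2 and 2. The 3 mitochondrial ribosomal genes, MRPL58, MRPL52 and MRPL36, lost their calls with each array left out except GFP-MFRP replicate 2, with an adjusted p of up to 0.183, 0.222 and 0.187, and without GFP-MFRP replicate 2 the count was 8. They also lost them with repeated quantile normalisation (limma adjusted p = 0.052, 0.0569 and 0.0541) and cyclic loess (0.106, 0.111 and 0.112), but not with a common median. With cyclic loess RRP8 and RRP7A lost theirs (0.0892 and 0.0909), while RRP12 and RRP1B kept theirs. CEP57, SMC3, RRP12, MRPL52 and MRPL36 were read by _s_at sets and CEP97 by an _x_at set, and another probe set of RRP12 lay at -0.00 and of CEP152 at -0.02.

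Hair keratin-associated genes and homeobox genes changed in a few members and not as families (camera adjusted p = 0.446 for KRTAP, 0.373 for HOXB and 0.976 for HOXC), at shares near the 10.0% called among all genes. Besides KRTAP1-5, its neighbour in name KRTAP1-1 rose from 3.63 ± 0.06, near the lower quartile of the arrays, to 5.24 ± 0.14 (SD, n = 3 each), and KRTAP1-3 rose by 0.45 ± 0.10 (SE). With KRTAP4-12, whose means in both groups, 2.62 in control cells, lie under the lower quartile and are not shown to exceed background, 4 of 34 genes with the stem KRTAP were called higher and none lower. Of 28 HOX genes 3 fell and none rose, HOXB3, HOXC6 and HOXB6, the last by 0.73 ± 0.20 (SE). The call of KRTAP1-3 was lost without control replicate 1, 2 or 3 (adjusted p = 0.0613, 0.112 and 0.0873) or GFP-MFRP replicate 3 (0.0581), and that of KRTAP4-12 without control replicate 1, 2 or 3 (0.0794, 0.0506 and 0.106). HOXB6 kept its call only without GFP-MFRP replicate 1, with an adjusted p of 0.14, 0.0689 and 0.118 without control replicates 1, 2 and 3 and 0.0608 without GFP-MFRP replicate 2 or 3. HOXC6 kept its call only without control replicate 1, with 0.178 and 0.172 without control replicates 2 and 3 and 0.0891, 0.0805 and 0.0723 without GFP-MFRP replicates 1, 2 and 3. KRTAP1-1, HOXB6 and HOXC6 were read by _s_at sets and KRTAP1-3 by an _x_at set.

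Long genes were lower relative to short genes in GFP-MFRP cells, while the median difference of the longest genes, -0.07, was -0.01 without GFP-MFRP replicate 1. On each array the deviation of a gene from its mean over the 6 arrays was fitted on log10 gene length. The slope differed by -0.142 between the groups (exact permutation p = 0.1, the smallest that 6 arrays can give). Slopes were 0.05, 0.10 and 0.07 on the control arrays and -0.16, 0.02 and -0.07 on the GFP-MFRP arrays. They are relative to the mean of all arrays and do not show how level itself runs with length in either group. With the length trend removed the cilium list still shifted downward (camera adjusted p = 0.000452, median -0.22 before and -0.16 after, 1.73e-05 to 0.0901 over its alternatives). The removal could hardly test length for this list, whose median length was 52.3 kb. The bin of genes with a median length of 50.4 kb had a median difference of 0.02. Even the bin of the longest genes, at -0.07, did not fall as far as the list. The proliferation list also did (camera adjusted p = 0.00285, median -0.12 before and -0.17 after, 0.00106 to 0.636 over its alternatives). For it the removal could not test length, since the trend gives no fall at its median length of 23.4 kb. The bin of genes with a median length of 26.5 kb had a median difference of 0.08. The slope itself stays open: RNA integrity or labelling may differ between single arrays, most of all GFP-MFRP replicate 1, since the arrays were not compared for RNA quality, and an effect of the construct was not tested.

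The joint C1QTNF5 and MFRP probe sets changed little for cells that overexpress MFRP. A wrong group label on 1 array is argued against: on 500 genes chosen without the array in question, where control arrays would lie at 0 and GFP-MFRP arrays at 1, the GFP-MFRP arrays lay at 0.849, 0.65 and 1.12 and the control arrays at 0.0770, 0.0149 and 0.0306. The probes may lie outside the sequence that the construct carries, which stays open, since no probe sequence was compared and the larger difference was 0.613. How strongly the transgene was expressed was not tested.

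For the fall of NF-kB cytokines and chemokines, blood cells in the control cultures and the length trend were examined as sources. The cells are a cultured line immortalised with telomerase, a design with no source of blood cells. The markers add no test of this. The 15 haematopoietic markers had a median log2 difference of 0.0312 (-0.31 for CSF1R to 0.40 for TYROBP). None was called lower by limma, where CCL2 differed by -5.12. Several markers, such as PTPRC at 3.54 in control cells, lie under the lower quartile and are not shown to exceed background, so their small differences decide nothing. The list also fell with the length trend removed (camera adjusted p = 1.55e-05, 1.55e-05 to 0.0901 over its alternatives), but that could not test length. Its members had a median length of 7.72 kb. Among genes with a mean of at least 6, the bin with a median length of 7.44 kb had a median difference of 0.11. The trend would thus give a rise at that length and not a fall. An effect of MFRP, of the construct's other parts or of a separate history of the cell cultures stays open, as the design has no further control.

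The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The split by label gave 1984 genes, 3365 probe sets and 10 lists, and the highest of the others gave 0, 0 and 3, so that 1 of the 10 splits reached each real count. Every other split has arrays of both groups on each side, so the difference between the groups widens its residual spread. Low counts of genes and probe sets there do not measure chance calls. For chromosomes the labels gave 0 by camera (2 at an unadjusted p under 0.05, 0 by fry), which all 10 splits reach, and the split of control replicate 1, GFP-MFRP replicate 1 and GFP-MFRP replicate 3 from the rest gave 7. With the correlation estimated, a test added after these counts were seen, that split gave 2 and every other split, the labels included, gave 0. What sets these arrays apart was not tested.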
